A study of Canis lupus familiaris with 36 samples.

How the data were processed

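RNA from 36 canine hemangiosarcoma samples was measured, 12 cultured cell lines and 24 snap-frozen tumour tissues, each on 1 one-colour Agilent canine array (design 021193). Per the labels' protocols, RNA was isolated with TriPure reagent and RNeasy columns, only RNA with an integrity number above 6.1 was used, and 500 ng of it was labelled with Cy3. Per the file headers, the deposited scanner tables were made with Agilent Feature Extraction 10.5.1.1 under protocol GE1_105_Dec08 and give intensity values for each spot on a linear scale. The processed signal used here is the scanner software's background-subtracted and spatially detrended intensity, per the file headers, and is not normalized between arrays. The same tables hold 0 or 1 marks for each spot, per the file headers, of which those for well above background, saturated and outlying were used. The authors also deposited a table of 1 intensity per spot and array, for which no header or label states the processing. Within each array its values had the same order as the median spot signal (Spearman correlation 1.0), and its column medians were 147 to 148, so it holds quantile-like normalized median intensities on a linear scale with no background subtraction.

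Each array carried 43803 non-control spots for 43603 different probes, and 1417 control spots were left out. Outlying spots, 2 to 18 per array, were set to missing, and no spot was saturated. The processed signal was put on a log2 scale and each array's 75th percentile was subtracted. Repeat spots of a probe were averaged. A probe entered a comparison if it was well above background on at least 6 arrays for the cell lines and for the comparisons over all arrays, 12 for the tissues, and 5 for the organs of origin, where the 1 lung tissue was not counted as a group. Where a gene had several probes, the one with the highest mean over the arrays compared was used. Where every array of a group was not well above background, the log2 difference of the signals is given with a bound of at least N-fold, from the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest well-above-background signal and the probe's own.

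Gene names came from matching each probe's accession, without version, to a gene table of assembly UU_Cfam_GSD_1.0, which was used for names only. A symbol was found for 1313 of 43603 probes, which gave 832 different symbols. The match succeeded for 1312 of 1411 probes with a curated RefSeq accession and for 0 of 17073 with a predicted one, and 25119 probes carry other identifiers. The remaining 42290 probes were tested under the identifier in the files.

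Cell lines and tissues were compared between the submitters' IL-8-high and IL-8-low groups in separate fits. The difference between the tissue and cell line contrasts (the interaction) and the difference between tissues and cell lines were fitted over all 36 arrays as 4 groups. Heart and liver tissues were compared with spleen tissues with the IL-8 group as a covariate. Tests were two-sided and used lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05 on the adjusted p, and every adjusted p of a gene below is from limma. CXCL8 was left out of the counts of the IL-8 comparisons within lines and within tissues, because the groups were set on it. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation, and fry, which asks whether a list's genes move on balance one way, were alternatives. Unlike camera, fry does not ask whether they move more than other genes. Of 24 lists, those with at least 3 measured genes were tested. The lists were measured only in part. By name the array held 13 of 31 inflammatory, 6 of 25 matrix, 5 of 20 coagulation, 4 of 19 protease and 4 of 26 endothelial genes.

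The named genes were, among genes with a symbol, the 12 with the largest difference in each direction among those called (5 for the interaction and the organs). Where fewer than 5 were called in a direction, genes with the smallest p were added up to 5 and are given as not passing. For each list up to 4 called members with the smallest p were added, or 1 or 2 members if none was called, as were CXCL8, CXCR1 and CXCR2 where measured. Some genes that this rule names are not reported here. The groups, comparisons, lists, this rule and 118 alternatives were fixed before the data were examined. A count of samples given with a gene's difference is that of the first group's samples beyond the other group's mean, so the groups can overlap.

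The alternatives included normexp background correction (offset 50), quantile normalization, the authors' deposited values, other filters on dim probes, the mean of a gene's probes, array weights, a trended and robust eBayes, slide or title stem as a block, origin or breed as a covariate, the CXCL8 level as a continuous predictor, and each array left out in turn. The files hold no mean signal column used here, so normexp was run on the median spot and background signals. The arrays lay on 11 slides and were scanned on 2 days. The first day held the 12 lines and 10 tissues (6 high, 4 low), and the second held 14 tissues (6 high, 8 low). Scan day as a block, each scan day alone, and the omission of 4 tissues rich in hepatocyte transcripts were added after the data were seen. No comparison was run within single slides, which held few arrays of each group. Random blocks used statmod 1.5.0, tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Missing values were filled with the gene's mean in the same group for the list tests, and with its mean over the arrays compared for correlations and regrouped samples.

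The procedure was tested on simulated data with 200 genes changed among those of each comparison. Of 100 genes changed by 1 and 100 changed by 2 on the log2 scale, 21 and 68 were recovered over 15963 genes for the cell lines, 40 and 87 over 16607 for the tissues, and 3 and 60 over 19694 for the interaction. The recovered numbers were 48 and 89 over the same 19694 genes for tissues against cell lines, 24 and 74 over 19111 for heart, and 15 and 67 over 19111 for liver, with 3 to 9 false calls. The simulated noise was independent between genes and between arrays. Correlation between genes or arrays was thus not covered, and these numbers may not hold for the real arrays. No pair of arrays held identical values. The labels do not say whether samples with a shared title stem came from 1 dog, and the 12 lines have 7 stems and the 24 tissues 20. The p-values therefore measure the spread between these arrays, which can be smaller than that between dogs.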

Results

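Gene expression was profiled in canine hemangiosarcoma, a malignant tumour of blood vessel-forming cells, with the aim of comparing tumours with high and low interleukin-8 (IL-8). The 36 arrays comprised 12 cell lines (6 IL-8-high, 6 IL-8-low) and 24 tumour tissues (12 IL-8-high, 12 IL-8-low), which the submitters divided at the median IL-8 level. The tissues came from spleen (11), heart (7), liver (5) and lung (1), and the groups were unequal: 5 of 7 heart tissues were IL-8-high, 4 of 5 liver tissues were IL-8-low, and Golden Retrievers gave 6 of 12 high and 11 of 12 low tissues. On average 48.7% ± 4.13 (SD, n = 36) of an array's spots lay well above background, with a range of 38.3% to 57.7%. The 75th percentile of the processed signal was 336 ± 90.9 in cell lines (SD, n = 12) and 222 ± 83.1 in tissues (SD, n = 24). The number of arrays limits the precision.

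CXCL8, which encodes IL-8, a chemokine that attracts neutrophils, followed the labels, as the groups had been set on it. In tissues its level was 4.73 ± 0.94 (SD, n = 12) in the high and 1.48 ± 1.06 (n = 12) in the low group, on a log2 scale relative to each array's 75th percentile. All 12 high tissues lay above the low group's mean. The difference was 3.25 (SE 0.39, adjusted p = 1.9e-04), and 3.18 with scan day as a block. Within the first scan day it was 3.07 and within the second 3.25, without passing in either (adjusted p = 0.369 and 0.055, with 5.6e-05 to 0.369 over the alternatives that left out no single array). In cell lines the level was 1.37 ± 0.45 (n = 6) against -1.04 ± 1.53 (n = 6), and 6 of 6 high lines lay above the low lines' mean. The difference of 2.41 (SE 0.59) did not pass the threshold over all genes (adjusted p = 0.823). On this probe IL-8-low tissue 8 and IL-8-high tissue 12 lay on the other side of the tissue median. Each of the 3 other CXCL8 probes misplaced 2 tissues, and 2 of these probes misplaced IL-8-low line 1 and IL-8-high line 3.

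**Figure D1:**
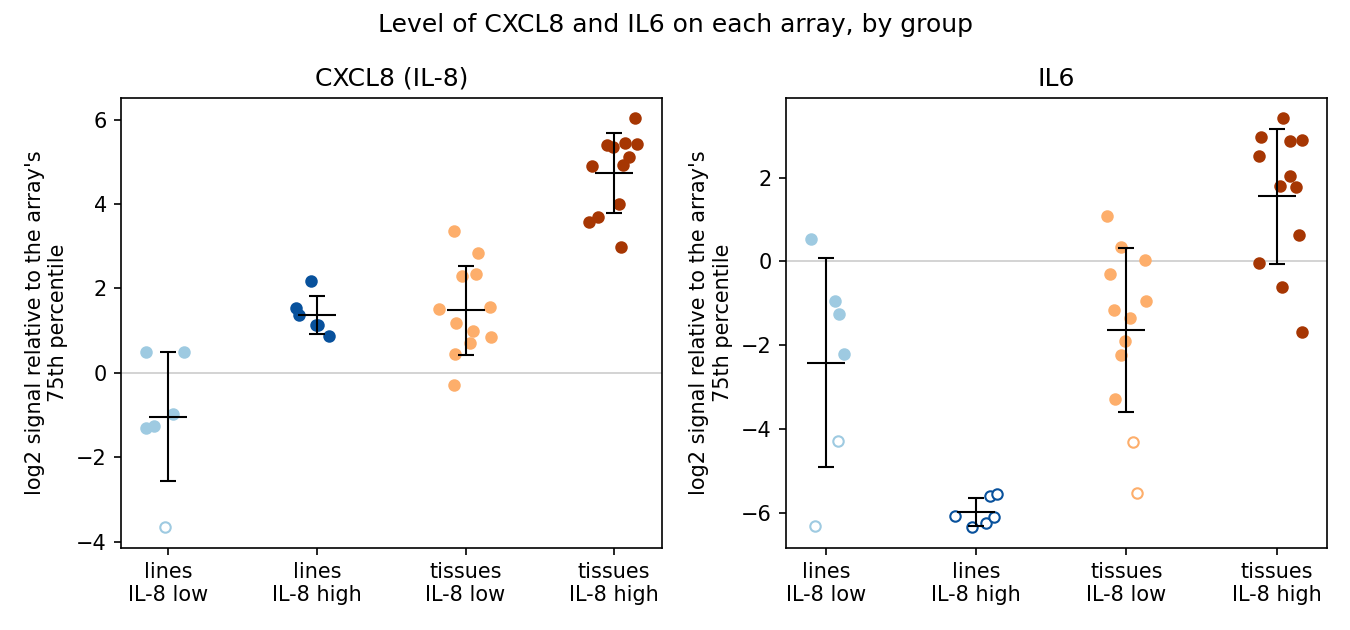
Each point is the log2 signal of CXCL8 or IL6 on 1 array, relative to the array's 75th percentile, in the 4 groups, with bars for the mean and SD and open points for spots not well above background. IL6 was higher in IL-8-high than in IL-8-low tissues (1.55 against -1.63) and not well above background in 6 of 6 IL-8-high lines.

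Lists of inflammatory, matrix, coagulation and protease genes were higher in IL-8-high than in IL-8-low tissues when the genes of a list were taken as nearly independent. With an estimated correlation between them no list passed (adjusted p = 0.081, 0.248, 0.081 and 0.189), and no member passed over all genes. Of 8 measured cytokines and NF-kB targets 7 were higher, by a mean of 1.33 on the log2 scale, led by the cytokines IL6 (3.18, SE 0.69, higher than the low group's mean in 11 of 12 high tissues) and IL1A (1.57, 12 of 12). All 6 measured fibroblast and matrix genes were higher, by a mean of 1.04, among them the collagen gene COL1A1 (1.84) and the collagen-binding proteoglycan gene DCN (1.80). All 4 measured coagulation and fibrinolysis genes were higher, by a mean of 0.94, including F3, the tissue factor that starts clotting (1.60), and ANXA2, a receptor for plasminogen and its activator (0.98). The 3 measured matrix protease and inhibitor genes were higher by a mean of 0.92, with the metalloproteinase inhibitor TIMP1 at 1.25 and the collagen-degrading cathepsin CTSK at 0.99.

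These 4 of the 10 lists tested rose by camera, with adjusted p = 0.0076 for the inflammatory, 0.019 for the matrix, 0.027 for the coagulation and 0.030 for the protease list. None passed with an estimated correlation, as given above. By fry, the inflammatory, coagulation and protease lists passed (adjusted p = 0.0071, 0.0071 and 0.027) and the matrix list had 0.079. The mean shifts of the 4 lists were 0.72, 0.90, 0.93 and 0.94 with normexp and 0.69, 0.89, 0.87 and 0.90 in the authors' deposited values, so that of the inflammatory list was smaller there, and all passed. Adjusted over the list alone, 2 inflammatory, 3 matrix, 1 coagulation and 0 protease genes passed, against 0 over all genes. With scan day as a block the mean shifts of the 4 lists were 1.26, 1.07, 0.91 and 0.90 and all passed. Within the second scan day they were 1.34, 1.73, 1.34 and 1.21 and all passed, and within the first they were 0.80, 0.12, 0.29 and 0.65 and none passed. Transcripts of hepatocytes were high in 4 tissues, all IL-8-low (tissues 5, 6, 10 and 11). All 4 were scanned on the second day, so differences between the scan days cannot be told apart from differences due to these tissues. Without these the shifts of the 4 lists were 0.87, 0.75, 0.65 and 0.84, and the matrix and coagulation lists no longer passed (adjusted p = 0.087 each). With origin as a covariate only the inflammatory list passed (adjusted p = 0.049, against 0.093 for the matrix list), and with breed as a covariate the coagulation and protease lists did not (0.072 and 0.071). Over the alternatives that left out no single array the adjusted p ranged from 0.0011 to 0.444 for the inflammatory, 0.000995 to 0.769 for the matrix, 0.0022 to 0.680 for the coagulation and 0.0062 to 0.469 for the protease list. With each array left out in turn the first 3 always passed, and the protease list was lost in 6 of 24 fits (adjusted p up to 0.070).

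The other lists did not pass camera in this comparison. Neutrophil markers had a mean difference of 0.45 (adjusted p = 0.407), with MMP9 at 1.23. Endothelial markers were higher in 4 of 4 genes (mean 0.54, adjusted p = 0.182), with CD34 at 0.91 and VWF at 0.71. MHC class II genes were lower in 6 of 7 (mean -0.28, adjusted p = 0.280), macrophage markers had a mean of -0.04 (0.854), and interferon response genes a mean of -0.57 (0.203), with the antiviral genes OAS1 at -0.96 and MX1 at -0.97. Immediate early and heat shock genes had a mean of 0.51 (0.132) and passed by fry (0.027), with the nuclear receptor gene NR4A1 at 1.27. The hypoxia-responsive vasodilator gene ADM lay 1.42 higher and VEGFA 0.38, the proliferation gene BIRC5 -0.03, and the liver apolipoprotein gene APOH -3.16 (SE 1.83), with the 4 highest values in the tissues named above.

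Gene by gene, 12 of 16606 genes passed in tissues (11 higher, 1 lower) and 2147 had p under 0.05. None of the 502 tested genes with a symbol was among the 12. TC68320 rose by 1.75 (SE 0.29) and XM_546802 by 1.64 (SE 0.28), both with adjusted p = 0.019 and an identifier in place of a name, and XM_539639 fell by 1.14 (SE 0.22, adjusted p = 0.038). These 3 were chosen after their values were seen. XM_539639 was -0.42 with normexp and -0.47 in the authors' deposited values, and its call was kept in 2 of 11 alternatives and lost in 16 of 24 fits with a tissue left out. Over the same alternatives TC68320 ranged from 0.91 to 2.19 and XM_546802 from 0.86 to 2.09. Their calls were each kept in 5 of 11 (limma adjusted p up to 0.738). With a tissue left out, both calls were lost only without IL-8-high tissue 8. Closest among named genes were IL6 (adjusted p = 0.065), SULF2, which trims heparan sulfate (1.51, SE 0.36, adjusted p = 0.098, 12 of 12 tissues), MCPH1 (0.75, adjusted p = 0.130) and the IgG receptor gene FCGR1A (1.47, SE 0.38, adjusted p = 0.139, 12 of 12). Lower, without passing, were the betaine transporter gene SLC6A12 (-1.46), the steroid dehydrogenase gene HSD17B14 (-2.44), the sodium pump subunit gene ATP1B1 (-1.06) and the superoxide dismutase gene SOD1 (-0.91). The count was 3 with scan day as a block, 0 and 7 within the 2 scan days, 3 with origin and 0 with breed as a covariate, and 0 without the 4 tissues rich in hepatocyte transcripts. It ranged from 0 without IL-8-high tissue 8 to 50 without IL-8-low tissue 1.

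In the cell lines no gene separated the IL-8 groups after adjustment. The prostaglandin E2 receptor gene PTGER4 was lower in 6 of 6 IL-8-high lines (-1.76, SE 0.40, adjusted p = 0.823), as were the anti-apoptotic gene BCL2L2 (-1.04), the cholesterol transporter gene NPC1 (-0.61) and the bradykinin receptor gene BDKRB2 (-1.17), and the gap junction gene GJA1 (-1.21) in 5 of 6. The caveolae gene CAV1 (0.86, adjusted p = 0.996) was higher in 5 of 6. For NHLRC1 (0.85) the gene's other probe had the opposite sign. The metalloproteinase inhibitor gene TIMP2 lay at -0.98 and was the 1 gene to pass when adjusted over the list alone.

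By limma, 0 of 15962 genes passed in the lines and 721 had p under 0.05, a smaller share than the 0.05 that chance alone would give. Of 6 lists none passed: fibroblast and matrix genes were lower in 5 of 6 (mean -0.38, adjusted p = 0.459), inflammatory genes had a mean of 0.25 (0.738), immediate early genes 0.18 (0.738) and coagulation genes -0.12 (0.907). The protease list had a mean of 0.25 while camera ranked it downward (0.907), and endothelial markers had a mean of -0.03 and a median of 0.18 (0.950). All lines were scanned on the first day.

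IL6 went with IL-8 in opposite directions in tissues and lines. This difference passed in the main fit but in 0 of 7 alternatives that left out no single array. Its log2 difference between IL-8-high and IL-8-low samples was 3.18 in tissues and -3.57 in lines, where the cytokine's transcript was not well above background in 6 of 6 high lines and well above it in 4 of 6 low lines (at least 2.93-fold lower in the high lines). The interaction was 6.75 (SE 1.21, adjusted p = 0.040). High and low did not stand for the same CXCL8 level in both materials, with a mean of 1.37 in high lines and 1.48 in low tissues. Lines titled GM, JLU and JLI were IL-8-high and the tissues of these titles IL-8-low, whereas FH was high in both. The 6 high and the 6 low lines had 4 title stems each, so counts of lines may not be counts of dogs. IL-8-low lines 3 and 4 shared a stem and the labelled origin heart, with IL6 at -4.28 (not well above background) and 0.53. An unnamed transcript, ENSCAFT00000009949, was the other of 2 genes of 19694 that passed (3.64, SE 0.67, adjusted p = 0.040), and 1433 had p under 0.05. SULF2 (3.25, SE 0.62, adjusted p = 0.051, not well above background in 6 of 6 high lines and at least 1.42-fold lower there than in low lines), PTGER4 (3.25, SE 0.66, adjusted p = 0.092), GJA1 (2.39, adjusted p = 0.232) and the prostaglandin E synthase gene PTGES (3.95, SE 1.02, adjusted p = 0.239) had the same pair of signs, higher in IL-8-high tissues and lower in IL-8-high lines. ATP1B1 (-1.83) and SULT1A1 (-2.15) had the opposite pair, as had the growth factor receptor gene MET (-1.98), none of them passing.

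Of 15 lists, fibroblast and matrix genes (mean interaction 1.42, 6 of 6 positive, camera adjusted p = 0.026, adjusted p = 0.389 with an estimated correlation) and inflammatory genes (1.36, 8 of 11 positive, 0.0495, adjusted p = 0.257 with an estimated correlation) passed. Over all genes 0 and 1 members passed, and adjusted over the list alone 0 and 1. Coagulation genes had a mean of 1.05 (0.142), proteases 0.71 (0.168), endothelial markers 0.85 (0.296), interferon genes 0.91 (0.329) and hepatocyte genes -2.16 (0.285). With scan day as a block IL6 had an interaction of 6.62 (adjusted p = 0.063) and ENSCAFT00000009949 3.58 (0.063), the matrix list 1.45 (0.016) and the inflammatory list 1.31 (0.052). Within the first scan day, the only one to hold both materials, these were 6.04 (0.254), 3.64 (0.444), 0.50 (0.477) and 0.92 (0.278), and without the 4 tissues rich in hepatocyte transcripts 5.97 (0.121), 3.50 (0.155), 1.13 (0.088) and 1.11 (0.088). Over the alternatives that left out no single array the adjusted p ranged from 0.055 to 0.304 for IL6, 0.055 to 0.853 for ENSCAFT00000009949, 0.0056 to 0.477 for the matrix list and 0.018 to 0.278 for the inflammatory list. With each array left out in turn they ranged from 0.0036 to 0.115, 0.014 to 0.162, 0.0047 to 0.156 and 0.020 to 0.188, and the calls were lost in 17, 18, 6 and 26 of 36 fits. The IL6 interaction was 3.33 with normexp and 3.003 in the authors' deposited values, without passing in either. The shift of the inflammatory list was 0.68 with normexp, which passed, 0.56 in the authors' deposited values and 1.37 with quantile normalization, which did not (adjusted p = 0.062 each).

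Tumour tissues carried far more transcript of immune and vascular genes than cell lines. MHC class II genes, which present antigen to T cells, rose in 7 of 7, led by DLA-DRA (10.10 on the log2 scale, SE 0.52, adjusted p = 5.5e-18, 24 of 24 tissues) and DLA-DQB1 (9.70). Macrophage markers rose in 4 of 4, with the costimulatory gene CD86 at 9.21 (at least 129-fold) and the scavenger receptor gene CD163 at 8.90 (at least 114-fold). Endothelial markers rose in 4 of 4, with the VEGF receptor gene KDR at 7.48, VWF at 5.20 and CD34 at 4.17. Neutrophil markers rose in 5 of 5, with the antimicrobial peptide gene CAMP at 6.81 and MMP9 at 5.86.

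Among the named genes with lower levels in tissues than in cell lines were the growth factor gene FGF5 (-5.09, at least 7.67-fold), the chromatin protein gene HMGA1 (-4.18), the cell cycle gene CCND1 (-2.84), the lymphatic marker PDPN (-3.51), the adenosine receptor gene ADORA2B (-3.87) and the prostaglandin synthase gene PTGS2 (-3.23). Of 6 fibroblast and matrix genes 4 fell, including DCN (-2.66), COL1A2 (-2.18) and BGN (-1.53), and 2 rose, PDGFRB by 1.74 among them. The coagulation genes F3 (-2.61) and ANXA2 (-1.75), the hypoxia-responsive genes VEGFA (-1.46) and ADM (-1.52), and TIMP1 (-0.98) fell as well, whereas BIRC5 (-0.26) did not pass.

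Inflammatory genes rose in 9 of 11 and fell in 1, with the endothelial adhesion genes SELE at 5.37 (at least 11.1-fold) and VCAM1 at 4.94, IL6 at 4.16 and the monocyte chemokine gene CCL2 at 3.34. Over the alternatives that left out no single array IL6 ranged from 1.64 to 4.68 and passed in 7 of 8 (limma adjusted p up to 0.057). CXCL8 itself rose by 2.94, and its receptor gene CXCR2, not well above background in any line, rose by an amount that these signals do not bound. Adipocyte genes rose in 3 of 3, with the fat cell regulator PPARG at 6.25, ADIPOQ at 2.06 (at least 1.39-fold) and LEP at 1.11. All 3 T and NK cell markers (CD4 at 2.66, at least 1.64-fold, CD8A at 2.07, at least 1.19-fold, and CCL5 at 2.15), all 3 interferon genes (MX1 at 5.89), all 4 hepatocyte genes (SERPINA1 at 9.08, at least 139-fold, and APOH at 4.67, at least 6.36-fold) and all 3 cardiomyocyte genes (TNNT2 at 3.95, at least 3.92-fold) rose singly. For APOH the level was 7.69 to 9.54 in the 4 tissues rich in hepatocyte transcripts and at most 1.04 in the other 20, whereas SERPINA1 was at least 0.21 in every tissue. Of the platelet genes GP1BA rose by 4.76 and ITGA2B by 1.41, whereas ITGB3 fell (-2.05). Markers of lists with fewer than 3 measured genes that rose were the epithelial gene CLDN3 (3.21), the erythroid gene RHAG (0.98), the smooth muscle gene DES (1.87) and the lung transcription factor gene NKX2-1 (0.96). RHAG lost its direction in the authors' deposited values (-0.02) and NKX2-1 with slide as a block (-0.18).

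**Figure D2:**
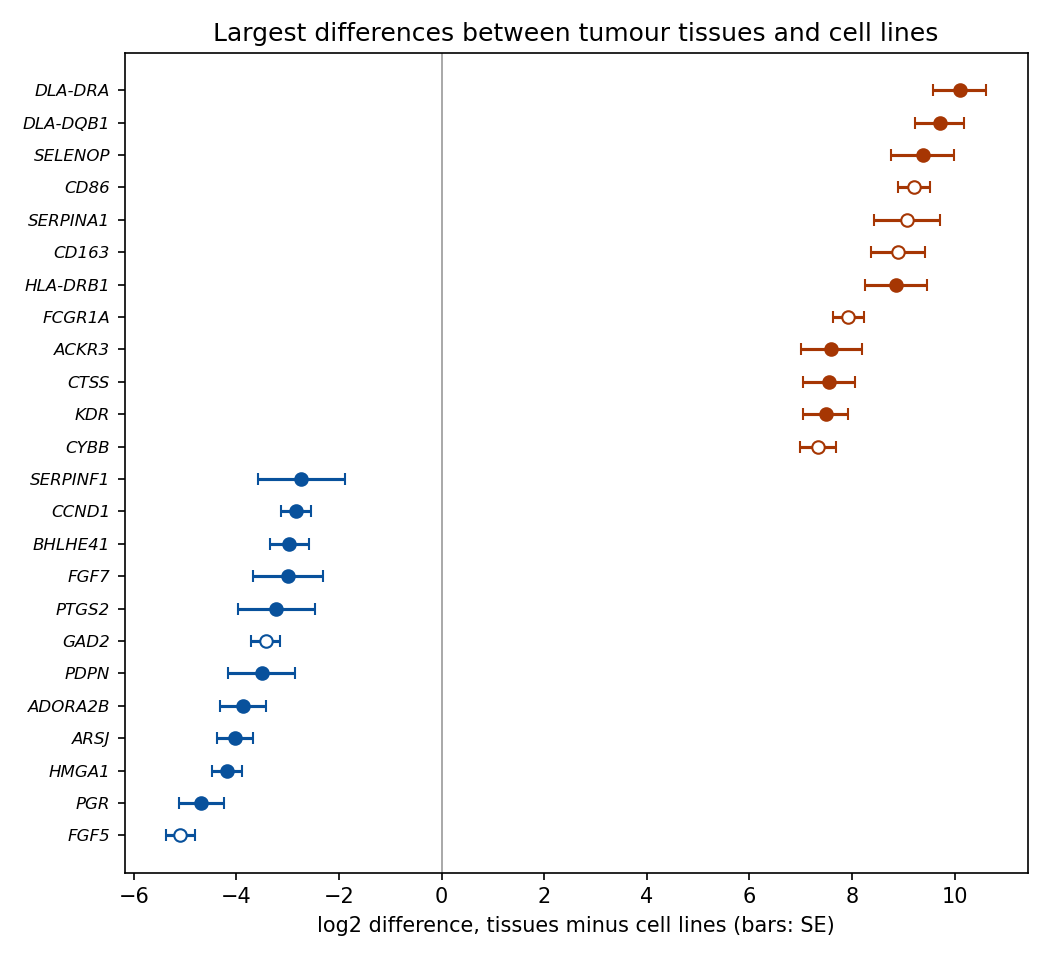
Points give the log2 difference, tissues minus cell lines, of the 12 named genes with the largest difference in each direction, with bars for the SE, and open points mark genes not well above background in one material. DLA-DRA was highest at 10.10 and FGF5 lowest at -5.09.

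By limma, 13695 of 19694 genes passed (6691 higher and 7004 lower in tissues), among them 457 of 594 with a symbol. The median over all genes was -0.07 and moved by 0.24 with normexp. Of the called genes 48.9% were higher, against 57.8% with normexp, 44.0% with quantile normalization and 41.3% in the authors' deposited values. The count was 11425 with scan day as a block, 10674 within the first scan day, which held all lines and 10 tissues, and 13073 without the 4 tissues rich in hepatocyte transcripts. Of 15 lists 6 passed camera: MHC class II (mean 6.91, adjusted p = 8.6e-06), macrophage (7.18, 2.3e-04), endothelial (4.55, 0.0011), neutrophil (4.21, 0.0060), inflammatory (2.24, 0.030) and adipocyte genes (3.14, 0.037). With an estimated correlation none passed, with adjusted p = 0.105 for the first 3, then adjusted p = 0.158, 0.132 and 0.113. Members passed in the same numbers when adjusted over the list alone. The mean shifts depended on the scaling: with normexp they were 4.54, 3.97, 3.81, 2.24, 1.26 and 1.60, and in the authors' deposited values 4.22, 3.50, 3.76, 1.57, 0.86 and 1.104, in the same order, and the adipocyte list passed in neither. With quantile normalization they were 6.59, 6.77, 4.45, 3.69, 1.87 and 2.71, and all passed. With scan day as a block the mean shifts were 7.26, 7.34, 4.54, 3.72, 2.41 and 2.79, and the adipocyte list no longer passed (adjusted p = 0.067, with 1.5e-14 to 0.113 over its alternatives that left out no single array). Within the first scan day the first 5 were 7.23, 7.28, 4.54, 5.04 and 2.44 and passed. The remaining lists did not pass camera: hepatocyte (mean 5.11, adjusted p = 0.087), T and NK cell (2.29, 0.082), interferon (2.73, 0.117), cardiomyocyte (2.64, 0.184), platelet (1.37, 0.475), immediate early (0.45, 0.748), coagulation (median -0.95, 0.395), matrix (-0.63, 0.485) and protease genes (-0.45, 0.567). By fry the 6 lists passed as well, as did the hepatocyte (adjusted p = 5.1e-06), T and NK cell (1.3e-09), interferon (3.7e-07), cardiomyocyte (2.3e-05), platelet (2.2e-04) and coagulation lists (1.1e-04, lower), but not the matrix (0.069), immediate early (0.090) and protease lists (0.090). With 13695 of 19694 genes called, passing fry does not show that a list differed more than other genes.

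The cardiac muscle list was higher in heart than in spleen tissues by camera, though not with an estimated correlation (adjusted p = 0.348) or by fry (0.546). The mean level of 3 of its genes, those measured over all arrays, was 2.78 in IL-8-high tissue 5 and 2.77 in IL-8-low tissue 8, between -2.20 and -0.28 in the other 5 heart tissues, and between -3.31 and -0.20 in the spleen tissues. All 4 measured cardiomyocyte genes were higher, by a mean of 1.51, with the troponin gene TNNT2 at 2.99 (SE 0.96, higher in 7 of 7 heart tissues) and the calcium pump regulator PLN at 1.70. Fibroblast and matrix genes were higher in 6 of 6 (mean 0.85), with DCN at 1.66 and COL1A2 at 1.19, and proteases and inhibitors in 4 of 4 (mean 0.88), with CTSK at 1.43. The serotonin receptor gene HTR2B (1.46), the heparan sulfatase gene SULF1 (2.02) and the glutamate transporter gene SLC1A3 (2.72) were higher in 7 of 7. The mast cell receptor gene MS4A2 (-2.00) and the neutrophil peptide gene CAMP (-2.99) were lower.

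By camera the 3 lists passed (adjusted p = 0.0048, 0.0051 and 0.038), with adjusted p = 0.348, 0.365 and 0.348 with an estimated correlation and 0.546 each by fry. Adjusted over the list alone, 1 cardiomyocyte, 0 matrix and 1 protease gene passed. By limma 0 of 19111 genes passed, the genes named having adjusted p = 0.953. For 698 genes p was under 0.05, a smaller share than the 0.05 that chance alone would give. The cardiomyocyte shift was 0.71 both with normexp and in the authors' deposited values, and passed in each. With scan day as a block the 3 shifts were 1.52, 0.96 and 0.81 and passed. Within the first scan day they were 0.997 (adjusted p = 0.554), 1.17 (0.0059) and 1.59 (0.0082), and within the second 2.13 (3.2e-04), 0.97 (0.013) and 0.41 (0.398). The cardiomyocyte call ended without IL-8-low tissue 8 (highest adjusted p = 0.121) and the matrix call without IL-8-high tissue 8 (0.065). The protease call ended without any of 8 of 24 tissues (adjusted p up to 0.167): IL-8-high tissues 1, 4, 5, 8, 11 and IL-8-low tissues 4, 9, 11. Over the alternatives that left out no single array the adjusted p ranged from 9.8e-05 to 0.554, 8.3e-04 to 0.546 and 0.0013 to 0.546 for the 3 lists.

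Tissues labelled liver differed among themselves in liver transcripts, and no gene or list passed between them and spleen tissues, a comparison that recovered only 15 of 100 simulated genes changed 2-fold. The mean level of 4 hepatocyte genes (APOH, SERPINA1, CYP2E1 and F9) was 8.43 in IL-8-low tissue 11 and 8.41 in IL-8-low tissue 5, and -4.18, -2.36 and -2.24 in the other 3 tissues labelled liver. It was 7.02 in IL-8-low tissue 10 and 6.12 in IL-8-low tissue 6, both labelled spleen, and at most 0.45 in the other 20 tissues. The hepatocyte list had a mean difference of 1.71 (adjusted p = 0.222). Inflammatory (-0.72), MHC class II (-0.73, 7 of 7 lower) and matrix genes (-0.78, 5 of 6 lower) had adjusted p = 0.074 each, and 0 of 15 lists passed. Adjusted over the list alone, 1 protease or inhibitor gene was lower. By limma 0 of 19111 genes passed and 902 had p under 0.05, a smaller share than the 0.05 that chance alone would give. The muscle gene DMD (1.53, SE 0.32, adjusted p = 0.640, 5 of 5 higher) and the leukocyte enzyme gene CD38 (-1.56, SE 0.43, adjusted p = 0.961, 5 of 5 lower) came closest. With scan day as a block 0 genes passed, as within each scan day and without the 4 tissues rich in hepatocyte transcripts.

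**Figure D3:**
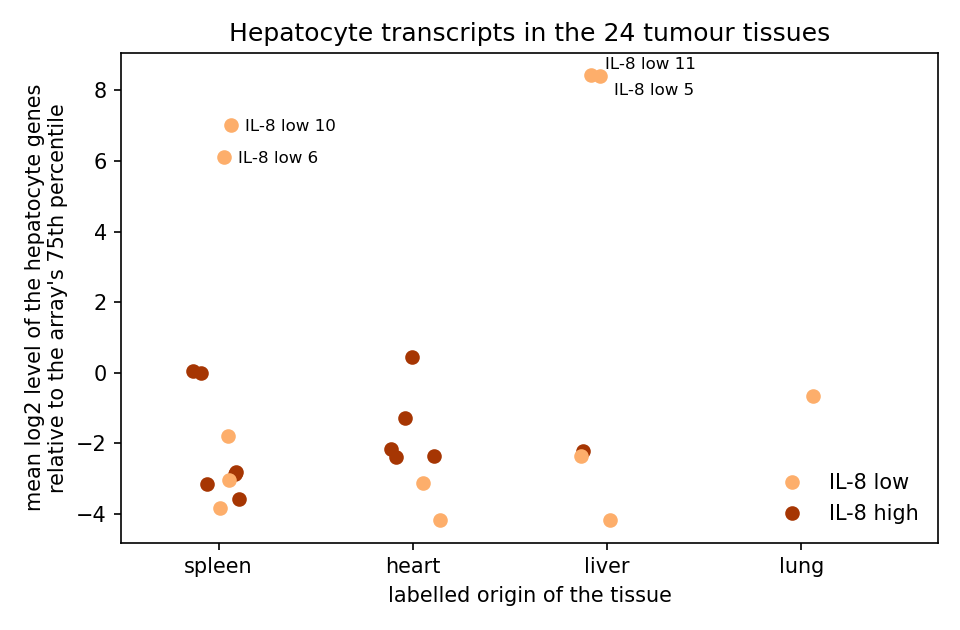
Each point is the mean log2 level of the hepatocyte genes in 1 tissue, relative to the array's 75th percentile, by labelled organ of origin and coloured by IL-8 group. The 4 named IL-8-low tissues lie between 6.12 and 8.43 and the other 20 at or below 0.45.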

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

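The tests of regrouped samples for the first 4 comparisons, of host organ, of breed and of shared dogs were written down before their results were seen, and all other tests in this part afterwards. Among 189 sets of values, 9 held 1 sample far from the others of its group, and about 1 in 20 sets would by chance. In cell lines these were GJA1 at 0.80 in IL-8-high line 3 (nearest other -0.57), BIRC3 at -0.29, TNNI3 at -6.39 and VEGFA at 2.73 in IL-8-low line 1 (-1.83, -0.79 and 4.70), and OAS2 at 3.56 in IL-8-low line 6 (2.40). The share of spots well above background was 44.0% in IL-8-high line 5 (48.2%). In heart tissues NKX2-5 was -1.83 and MS4A1 -1.62 in IL-8-high tissue 6 (-5.15 and -5.23), and VCAM1 was -3.72 in IL-8-low tissue 1 (0.57). The IL-8 difference in tissues minus that in lines was 3.64 for ENSCAFT00000009949, 6.75 for IL6, 1.36 for the inflammatory and 1.42 for the matrix list.

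Samples were also regrouped at random into groups of the same sizes. Of 100 groupings, the real one included, 2 gave at least the 12 genes called between IL-8-high and IL-8-low tissues, the other giving 2257 with all 4 tissues rich in hepatocyte transcripts in 1 group. For tissues against lines only the real grouping (1 of 100) gave its 13695 genes, and the highest other count was 2068. For the interaction 12 of 100 gave at least its 2 genes, with up to 60, so chance was not excluded for that count. For the lines, heart and liver comparisons, which called 0 genes, all 100 did, with up to 66, 3 and 2283.

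The 12 genes called between IL-8-high and IL-8-low tissues could reflect IL-8 biology, the unequal organs of origin, breed, or the 4 hepatocyte-rich tissues, all IL-8-low. Origin as a covariate, with the lung tissue left out, left 3 genes past the threshold (18 with only that tissue left out). Yet the 12 genes kept a median of 0.994 of their difference (0.847 to 1.11, lower bound 0.604). Their median size was 1.81 (median SE 0.32) before and 1.91 (SE 0.35) after, which argues against the labelled origin as the cause. The labels did not follow hepatocyte content, as IL-8-low tissues 6 and 10, labelled spleen, were rich in hepatocyte transcripts. This covariate therefore cannot decide on the organ content of the samples. The count had been written down as the criterion, and by it origin would have been a cause. It fell although the sizes did not, so the sizes were used in its place, a choice made after the result was seen. Why the calls ended was not tested beyond the SE, which was 1.08 times as large. Breed as a covariate left 0 genes and a median of 0.923 of the difference (median size 1.75, SE 0.36), and omission of the 4 tissues 0.876 (0.680 to 1.08; median size 1.70, SE 0.36), with lower bounds of 0.492 and 0.483, whereas the hepatocyte level as a covariate left 0.955 with a lower bound of 0.567. Breed and these 4 tissues therefore stay open as a part of the difference, since both are unequal between the groups and the omission and the covariate fell on either side of 0.5.

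The IL-8 difference of IL6 was positive in tissues and negative in lines, which could reflect biology of the tumour's surroundings, the scan day, or signals near background in the lines. Within the first scan day, which held both materials, the interaction was 6.04, which argues against scan day as the cause. With every level raised to at least the array's lowest well-above-background signal, which raised 10 arrays, the interaction was 4.83 (SE 1.01). How much of the size comes from signals near background cannot be told apart, as the high lines gave only a bound. The labelled origins of the lines were also unequal, with spleen for 4 of 6 high and 2 of 6 low lines. The interaction was not adjusted for origin or for shared title stems here.

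IL-8-low tissues 6 and 10 are labelled spleen and held hepatocyte transcripts, which could come from liver cells in the samples, a small carry-over of liver RNA, or exchanged origin labels. Over 16607 genes their deviations from the tissue median correlated with those of IL-8-low tissue 5, labelled liver, at 0.610 and 0.721 (0.854 for IL-8-low tissue 11), against -0.332 to 0.269 for the other 20 tissues. Liver cells in the samples would give this, but carried-over liver RNA or exchanged labels could as well, so the correlation does not decide between them. The hepatocyte levels of IL-8-low tissues 6 and 10 were 20.3% and 38.1% of that of tissue 5, which argues against a small carry-over. Of 5 tissues labelled liver, 3 lay below both, so an exchange of labels stays open. IL-8-low tissue 12, labelled liver with a level of -4.18, is 1 of these and shares a title stem with tissue 10 (7.02). The last title letters of these tissues, L and S, go with their origin labels.

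For the cell lines, the title stem as a random block, for lines that may share a dog, gave 0 genes as did the fit without it, which decides nothing. Arrays of lines correlated at a median of 0.968 in the 8 pairs with a shared stem (0.940 to 0.983). The median was 0.929 in the 58 other pairs (0.878 to 0.964). Each IL-8 group of 6 lines held 4 stems, and stem J was in both, so counts of lines may not be counts of dogs.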

How the results depend on the processing

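Scan day, the 4 hepatocyte-rich tissues left out, and the settings of the continuous predictor beyond its plain fit were chosen after seeing the data. The cause was not tested for any change below unless said. The 12 genes called in tissues became 0 with normexp, 24 with quantile normalization, 30 in the authors' deposited values, 3 with no filter on dim probes, 21 with probes well above background on every array, 23 with the mean of a gene's probes, 22 with a trended robust eBayes, 56 with array weights and 0 with slide as a fixed block. They were 27 with all 4 groups in 1 fit, 3 with origin, 3 in spleen tissues, 0 with breed, 0 in Golden Retrievers and 0 with origin and breed. They were 3 with scan day as a block, 0 on the first and 7 on the second scan day, and 0 without the 4 tissues. All 4 tissues were scanned on the second day. Where 0 passed limma, p was under 0.05 for 976 genes with normexp, 1419 with slide, 1185 with breed, 1545 in Golden Retrievers, 644 with origin and breed, 1154 on the first day and 1286 without the 4 tissues. Chance alone would give a share of 0.05 of the genes tested, and the 644 with origin and breed lie below that share. With CXCL8 as a continuous predictor the genes called in tissues were 507, then 173 with scan day as a block, 0 and 743 within the days, 55 with breed, 32 with origin and 1 without the 4 tissues.

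In the lines the count of 0 became 1 with array weights, 7 in spleen lines and 1 in Golden Retrievers. Spleen lines were taken by the origin label, and the last title letters of IL-8-low lines 5 (labelled spleen) and 6 (labelled brain) could stand for each other's organ, which the labels do not settle. For the interaction the count of 2 became 1 with normexp (another gene, negative), 1 with probes well above background on every array, 143 with array weights, and 0 with quantile normalization, the authors' deposited values, no filter, slide as a fixed block, title stem as a block, scan day as a block, the first scan day, or without the 4 tissues. For tissues against lines, 13695 became 25586 with no filter, 6620 with probes well above background on every array, 8070 at 2-fold or more, 8811 with slide as a block and 3113 with 4 paired titles. RHAG reversed to -0.018 in the authors' deposited values and NKX2-1 to -0.18 with slide as a block. In heart the count of 0 became 2 with array weights. CXCL8 in tissues was 3.07 (adjusted p = 0.369) on the first and 3.25 (adjusted p = 0.055) on the second scan day, with 5.6e-05 to 0.369 over its alternatives that left out no single array.

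With each array left out in turn the tissue count ranged from 0 to 50: 0 without IL-8-high tissue 8, 2 without IL-8-high tissues 1, 3, 4, 10 or IL-8-low tissues 5, 11, 3 without IL-8-low tissues 6, 12, 4 without IL-8-high tissues 7, 11 or IL-8-low tissues 7, 10, 7 without IL-8-high tissue 5, 19 without IL-8-low tissue 9, 21 without IL-8-high tissue 12, 35 without IL-8-low tissue 3 and 50 without IL-8-low tissue 1. The count in lines ranged from 0 to 1 (1 without IL-8-high lines 1 or 2), in heart from 0 to 1 (1 without IL-8-low tissue 1), and for tissues against lines from 13429 to 14037. The interaction count ranged from 0 to 11: 0 without IL-8-low lines 2, 4, 5, 6, IL-8-high lines 5, 6, IL-8-high tissues 3, 5, 7, 8, 9, 10 or IL-8-low tissues 3, 5, 8, 11, 1 without IL-8-high line 1 or IL-8-low tissue 1, 4 without IL-8-high line 3, IL-8-high tissue 2 or IL-8-low tissue 4, 7 without IL-8-low lines 1 or 3 and 11 without IL-8-high line 2. CXCL8 ranged from 1.89 to 2.72 in lines and from 3.09 to 3.42 in tissues, and the IL6 interaction from 6.16 to 7.53. The IL6 call ended without IL-8-high line 1 or any array that brought the interaction count to 0, and that of ENSCAFT00000009949 without any of these or IL-8-low tissue 1. The interaction's matrix list (1.17 to 1.73) lost its call without IL-8-high lines 1, 5, IL-8-low lines 5, 6 or IL-8-high tissues 4, 8. Its inflammatory list (1.01 to 1.47) kept its call only without IL-8-high line 2, IL-8-low line 1, IL-8-high tissues 1, 2, 5, 9, 11 or IL-8-low tissues 3, 4, 10. The protease list in tissues (0.78 to 1.05) lost its call without IL-8-low tissues 1, 4, 9 or IL-8-high tissues 6, 8, 10. XM_539639 (-1.23 to -1.03) lost its call without IL-8-high tissues 1, 2, 3, 4, 5, 7, 8, 9, 10, 11 or IL-8-low tissues 5, 6, 7, 10, 11, 12.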

Other observations

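The tests in this part were chosen after the data were seen, except the plain fit of CXCL8 as a continuous predictor. Across the 24 tissues single genes went with the CXCL8 level, and those named here were chosen after their values were seen. PTGES, whose enzyme makes prostaglandin E2, rose by 0.81 per unit of CXCL8 on the log2 scale (SE 0.13, adjusted p = 0.0057), IL6 by 0.97 (SE 0.15, adjusted p = 0.0057), the receptor gene PTGER4 by 0.45 (adjusted p = 0.016) and IL1A by 0.55 (adjusted p = 0.019). The antioxidant gene SOD1 fell by 0.31 (adjusted p = 0.025). In this fit 507 genes passed (261 rose, 246 fell). With 1 tissue left out the count ranged from 21 without IL-8-low tissue 5 and 100 without IL-8-low tissue 11 to 937 without IL-8-high tissue 10, while PTGES and IL6 passed each time (adjusted p up to 0.032). Without the 4 hepatocyte-rich tissues 1 gene passed, with slopes of 0.60 for PTGES (SE 0.15) and 0.78 for IL6 (SE 0.18), adjusted p = 0.290 and 0.243. Within the first scan day the slopes were 0.46 and 0.60 (adjusted p = 0.983 and 0.954) and within the second 1.04 and 1.15 (0.0036 and 0.013). The second day held all 4 hepatocyte-rich tissues, so scan day and these tissues cannot be told apart here. The other slopes were smaller without the 4 tissues, at 0.21 for PTGER4, 0.35 for IL1A and -0.08 for SOD1 (adjusted p = 0.537, 0.498 and 0.662), and within the first scan day, at 0.19, 0.40 and -0.02 (adjusted p = 0.998, 0.991 and 0.998). With scan day as a block SOD1 did not pass (adjusted p = 0.058). With breed as a covariate PTGER4 and SOD1 did not pass (0.067 and 0.091), and with origin PTGER4, IL1A and SOD1 did not (0.064, 0.163 and 0.076), whereas PTGES and IL6 passed with each (0.042 with breed and 0.047 with origin).

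Of 501 named genes, 36 correlated with CXCL8 at the adjusted threshold, 21 positively and 15 negatively, by 100000 resamplings. PTGES had r = 0.792 (p = 1e-05, the smallest possible, adjusted p = 0.0050) and a rank correlation of 0.792, and IL6 had 0.785 (adjusted p = 0.0050) and 0.761. For PTGES r was 0.524 over the 10 tissues of the first scan day, 0.915 over the 14 of the second, 0.660 without the 4 hepatocyte-rich tissues, and 0.621 and 0.683 within the IL-8-high and IL-8-low groups. For IL6 these were 0.604, 0.850, 0.702, 0.552 and 0.528. All 4 hepatocyte-rich tissues were among those of the second scan day. Without the 4 tissues the negative correlations of the liver enzyme gene CYP3A12 went from -0.604 to -0.0021 and of HSD17B14 from -0.640 to -0.188, so those tissues carried most of them.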
